A study of Glycine max and Zea mays with 6 samples.

How the data were processed

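The series holds 6 samples, each its own group with 1 library: soybean leaf H3K4me3, H3K56ac and H3K36me3, maize ear H3K4me1, and an input for each species. The inputs were not used here. Per the labels' protocols, soybean plants grew at 25 °C with 16 h of light and 8 h of dark and the 2nd and 3rd leaves were taken. Per the same protocols, tissue was fixed with 1% formaldehyde and the chromatin sonicated and immunoprecipitated. Antibodies against H3K4me3, H3K36me3 and H3K56ac are listed there; the one against H3K4me1 is not given in the sources used here. The design text of the series names H3K4me1 for soybean where the title and antibody label of the sample give H3K4me3, and the sample's labels were followed.

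The submitters' processing notes name Trimmomatic, Bowtie2, Picard, SICER and MACS2, with no versions, roles or order, and the build B73 RefGen_v4. Which caller made which list, its threshold, and whether the inputs entered the calls are not given in the sources used here. The deposited lists have 1 file per sample, so the authors' peaks are per sample as far as the files show. The deposited values are positions: chromosome, start and end in bp, with no score, fold, p-value or read count. Depth is therefore unknown, and a gene without a peak is a gene without a call, whatever its signal. The soybean H3K36me3 regions all start and end on a grid of 200 bp. In the maize list 2286 of 25301 regions have a start or an end off that grid. The files of these broad marks end a region on its last base counted from 0, and the ends were moved by 1 bp so that all lists were treated alike. Coordinates are printed counted from 1.

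No genome was used. Gene names and positions came from a RefSeq gene table of the soybean assembly Glycine_max_v4.0. The build of the soybean lists is not named in the sources used here apart from the maize build, which cannot be theirs, so the register of the lists against the gene table was tested. Windows of 5 Mb with fewer than 20 H3K4me3 peaks were left out. For the others, the share of H3K4me3 midpoints within 500 bp of a protein-coding gene end was taken. In 201 of 201 windows it was higher than its mean after shifts of the peaks by 20 kb and 100 kb in both directions. Per chromosome it was 34.0% to 41.4%, and the highest shifted value was 18.6%. The last peak of a chromosome lay at most 0.537 kb beyond the last annotated gene. On this ground peaks were overlapped with genes of the table. Its gene coordinates are not printed, and small differences between builds inside a window would pass this test. Gene positions for maize were not used here, so the planned comparisons of maize regions with genes and gene groups were not run.

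The plan was made before the data were examined and was departed from in several points. The table has no strand, so windows of 1 kb around the start of a gene were replaced by windows of 1 kb around either end. It has no product names, so the planned groups by product name were replaced by 44 groups of gene symbols, written after the list of symbols was seen and before any symbol was matched to a peak. The stricter threshold was the longer 50% of each list, which the plan named for lists without a score. The analyses of isolated genes, gene types, gene length and mark edges were added after the lists were seen. Of the tests of explanations, 2 on the maize regions off the 200 bp grid were run and then left out to hold the closing text to 3 patterns, and their values are given there without explanation.

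Peaks were counted as overlapping from 1 bp. Shares have exact (Clopper-Pearson) 95% intervals. Folds are over the median of 1000 random placements of the same lengths on the same chromosome. For distances to the ends of H3K36me3 regions, 1000 placements were used that overlapped the same region by at least 1 bp. A gene had H3K4me3 or H3K56ac when a peak overlapped either end ± 1 kb, and H3K36me3 when a region overlapped the gene by 1 bp. Covered lengths of H3K4me3 and H3K56ac for named genes include 1 kb either side of the gene. Groups were placed among 10000 random lists of the same size, drawn from the 2348 protein-coding genes with a symbol of their own and matched on length decile. The limits were those of the central 95% of the random lists, by percentile with tied lists counted equally below and above. The smallest group accepted was set at 9 genes after results were seen, which keeps PR1. With 1 library per mark there was no test between samples and no p-value across genes, and the intervals cover counting error only. Chromosome position used the extent from the first to the last peak of each list.

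Genes were named by a rule set beforehand: the listed symbols that were matched, members of each group with the longest covered length or the longest with no mark, the 5 longest peaks of each list, and the 5 longest H3K36me3 regions with both other marks and no annotated gene. Maize symbols of that rule were not looked up. From the listed symbols E3, GI, LOX1, ENOD40 and CRY1 were not matched as exact symbols or synonyms. Similar symbols, such as GIGANTEA, CRY1a, LOX1.1, ENOD40A and ENOD40B, were in the gene table and entered the symbol groups alone. The gene list and overlap functions were tested on simulated data. With planted overlaps of the soybean lists, the share found was within 0.159 percentage points of that expected from the planted share and the random background. Planted peaks were centred on their targets and the background came from the same functions, so this checks the counting alone. For gene lists of 30, 40 of 40 with a planted lower share and 40 of 40 with a planted higher share were called, and 1 of 40 with none. The planted shares lay far from the background, and simulated marks were independent between genes and unrelated to gene length. Smaller differences, length matching and related genes were therefore not tested by it. The work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives covered the overlap required, the longer part of each list, local random placement, window sizes, gene types, joined regions and matching of random lists.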

Results

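The series mapped histone H3 modifications by chromatin immunoprecipitation and sequencing (ChIP-seq) in 2 crop plants, with the aim named in its title of improving genome annotation. Leaves of soybean (Glycine max, William82, about 10 days old) were profiled for trimethylation of lysine 4 (H3K4me3), acetylation of lysine 56 (H3K56ac) and trimethylation of lysine 36 (H3K36me3). Ear primordia of maize (Zea mays), the young female inflorescences, 3 to 8 mm long, were profiled for monomethylation of lysine 4 (H3K4me1). In plants H3K4me3 is known as a mark of the 5′ ends of transcribed genes, and H3K36me3 and H3K4me1 as marks of the gene body. Each mark had 1 library, so no value below has a replicate check. Intervals are exact 95% binomial intervals, which cover counting error alone, and neighbouring peaks are not independent. Read depth is unknown, since the peak lists give positions alone. The 2 input samples were not analysed here.

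The soybean lists held 51233 H3K4me3 peaks with a median length of 860 bp, 60550 H3K56ac peaks with a median of 729 bp, and 32245 H3K36me3 regions with a median of 2400 bp. They covered 45.1 Mb, 49.4 Mb and 99.6 Mb. The maize list held 25301 H3K4me1 regions with a median length of 3800 bp, covering 117 Mb. All further soybean values are for the 20 chromosomes, which carried 51142, 60424 and 32195 of these peaks and regions.

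The first comparison asked how far the 3 soybean marks lay together. H3K4me3 and H3K56ac were found at largely shared places: 42129 of 51142 H3K4me3 peaks (82.4%, interval 82.0 to 82.7) overlapped an H3K56ac peak. Random placement on the same chromosome gave 10.5%, a 7.85-fold difference. In the other direction, 70.0% of H3K56ac peaks overlapped an H3K4me3 peak. H3K36me3 regions overlapped 56.4% of H3K4me3 peaks (interval 55.9 to 56.8, 4.13-fold over random placement) and 48.6% of H3K56ac peaks (interval 48.2 to 49.0, 3.61-fold). Of the H3K36me3 regions, 24268 of 32195 (75.4%, interval 74.9 to 75.8) carried both other marks, 4.87-fold above random placement. When peaks were placed at random within the same 1 Mb, which keeps local gene density, these 4 folds were 4.47, 2.43, 2.15 and 2.89. Peaks that lacked their partner were shorter. H3K4me3 peaks without H3K56ac had a median length of 364 bp against 962 bp with it, and H3K56ac peaks without H3K4me3 had 362 bp against 909 bp.

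The second comparison asked where H3K4me3 sat inside H3K36me3 regions. The median distance from the midpoint of an overlapping H3K4me3 peak to the nearer region end, on either side of it, was 588 bp (quartiles 405 and 769 bp). Within 1000 bp of an end lay 88.1% of midpoints, against 76.6% at random. Within 500 bp the share was 36.7% (interval 36.2 to 37.3), below the 52.6% of random placement, a ratio of 0.698. Random peaks had to overlap the same region by only 1 bp, so their midpoints could lie outside it. Overlapping H3K4me3 peaks had a median length of 1087 bp, and peak length also enters these shares. The ratio was 1.15 at 1000 bp and 0.393 at 250 bp, so its direction depended on the distance chosen. The outer edges of the marks came close together. The edge of the H3K4me3 peak was a median 76 bp from the edge of the H3K36me3 region, and 79.6% of these peaks had an edge within 200 bp of it. For H3K56ac the median was 98 bp and the share 72.3%. These edge distances were not set against random placement, and the edges of H3K36me3 regions lie on a grid of 200 bp. In the longer 50% of each list the share of H3K4me3 midpoints within 500 bp of an end was 14.3%.

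The third comparison set the soybean peaks against annotated genes, the question raised by the title of the series. H3K36me3 lay almost wholly at genes: 98.3% of its regions (interval 98.1 to 98.4) overlapped an annotated gene, against 39.4% at random, a 2.50-fold difference. For H3K4me3, 83.0% of peaks (interval 82.7 to 83.3) overlapped a window of 1 kb either side of a gene end, 2.99-fold over random placement. For H3K56ac this share was 74.8% (interval 74.5 to 75.1), 2.74-fold over random placement. Placed within the same 1 Mb, the 3 folds were 1.69, 1.92 and 1.77. The gene table gave no strand, so start and end of a gene could not be told apart in these counts.

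Of 46816 protein-coding genes, 73.1% carried H3K4me3 at an end, 69.5% carried H3K56ac at an end and 51.1% carried H3K36me3. All 3 marks were found at 23074 genes (49.3%, interval 48.8 to 49.7), 1.90 times the share that independent marks would give. No mark was found at 10390 genes (22.2%, interval 21.8 to 22.6), 5.54 times what independent marks would leave unmarked. The next largest class had H3K4me3 and H3K56ac without H3K36me3, with 7638 genes, followed by 3165 genes with H3K4me3 alone and 1688 with H3K56ac alone. H3K36me3 without either narrow mark at an end was seen at 356 genes. These classes count H3K4me3 and H3K56ac at gene ends alone, so a gene can hold such a peak farther inside. With the longer 50% of each list, 25.0% of genes carried all 3 marks.

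Marked genes were longer. Genes with all 3 marks had a median length of 4385 bp and genes with none 1836 bp. The share with H3K36me3 rose from 11.3% in the shortest length decile, with a median length of 705 bp, to 76.9% in the longest decile. H3K4me3 rose from 35.9% to 86.4% in the ninth decile and was 82.8% in the longest decile. A longer gene is a larger target under these rules, since 1 bp of H3K36me3 was enough and the windows at the ends of a short gene overlap. The mean share of gene length under H3K36me3 went from 10.5% in the shortest decile to 50.4% in the longest. How much of the trend comes from target size was not tested.

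**Figure D1:**
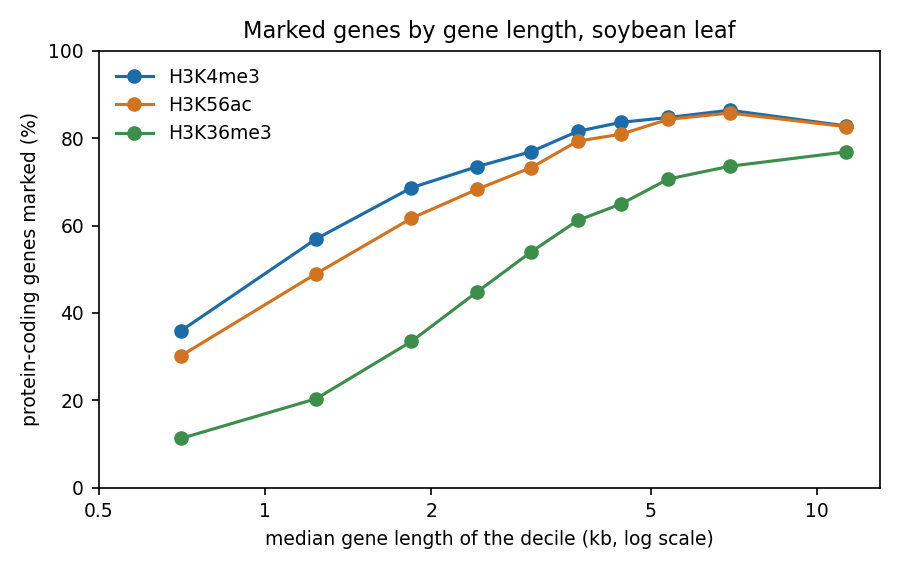
Share of soybean protein-coding genes carrying each mark (vertical axis, %) in the 10 deciles of gene length, placed at the median length of the decile (horizontal axis, kb, log scale). H3K36me3 goes from 11.3% to 76.9%, and H3K4me3 from 35.9% to 82.8%.

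Other annotated gene types carried the marks less often, with 1 exception. All 3 marks were found at 62.8% of 250 transcribed pseudogenes (interval 56.5 to 68.8), compared with 15.6% of 4482 other pseudogenes (interval 14.6 to 16.7). They were found at 21.6% of 3328 long non-coding RNA genes and at 2.23% of 448 ribosomal RNA genes. Genes of small nuclear RNAs, which act in splicing, showed H3K56ac at 68 of 133 (51.1%) and H3K4me3 at 46, but H3K36me3 at 6. Among 709 transfer RNA genes 41.0% had H3K56ac, 30.9% had H3K4me3 and 14.5% had H3K36me3. Among the 213 with no other gene within 2000 bp these shares were 17.8%, 6.57% and 0.469%, and 26 such small nuclear RNA genes had H3K56ac at 11, H3K4me3 at 6 and H3K36me3 at 0.

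Marks lay at 1 end of a gene rather than at both. Among 17281 protein-coding genes at least 2000 bp long with no other gene within 2000 bp, H3K4me3 was found within 500 bp of a single end in 67.8% (interval 67.1 to 68.5) and of both ends in 6.57%, where independent ends would give 16.4%. H3K56ac was at a single end in 58.5% and at both in 12.1%, closer to the 17.1% of independent ends. Where each of these marks was at a single end, it was the same end in 9101 of 9232 genes (98.6%, interval 98.3 to 98.8). H3K36me3 leaned to the same side. Of 8887 such genes with H3K4me3 at 1 end and any H3K36me3, 84.7% had more of the nearer 50% of the gene covered than of the farther 50%. The mean coverage was 84.7% ± 22.1 (SD over genes, n = 8887) on the near side and 47.9% ± 32.7 on the far side. Along the 11714 genes with H3K4me3 at a single end, H3K36me3 was present in 70.9% at its highest point, 7.5% of the way into the gene, in 55.0% just past the middle and in 8.28% at the far end. H3K56ac was highest in the first bin of the gene, at 73.6%, and fell to 7.88% just past the middle.

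**Figure D2:**
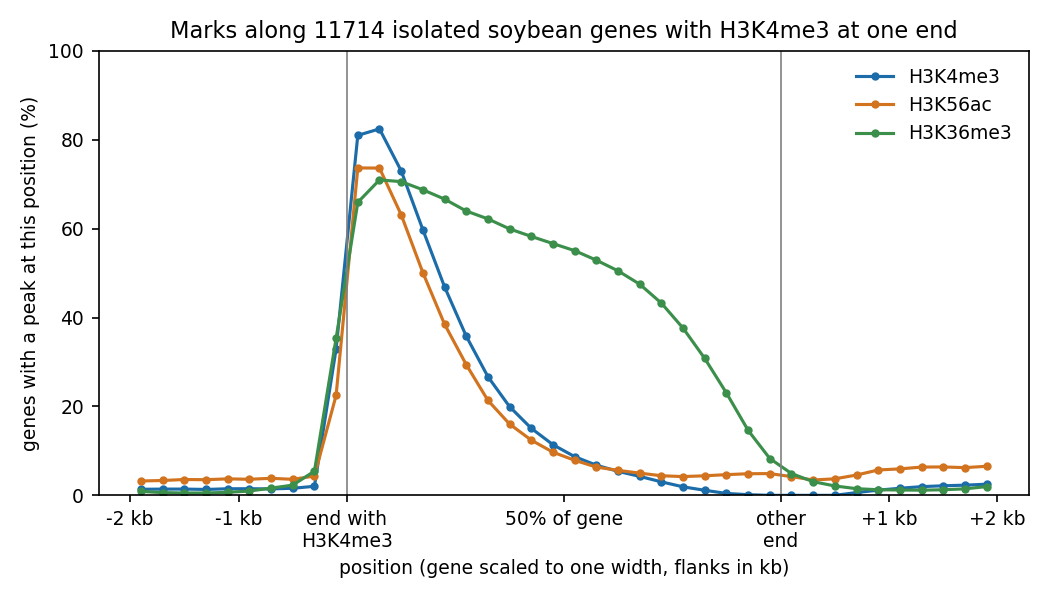
Share of 11714 isolated soybean genes with a peak of each mark at each position (vertical axis, %), with genes scaled to one width in 20 bins and flanks of 2000 bp on either side (horizontal axis). Genes were turned so that the end with H3K4me3 is on the left, which fixes the shape of the H3K4me3 line. H3K56ac reaches 73.6% in the first bin of the gene at that end. H3K36me3 goes from 70.9% in the next bin to 8.28% at the other end.

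Gene groups formed from gene symbols differed widely in their marks. Of 44 groups, 25 had a percentile outside the central 95% of random gene lists of the same size and length deciles. The percentile was that of the number of members with all 3 marks. There were 6 above and 19 below. About 2.2 groups would lie outside if the members of a group were independent draws. Genes of the same family need not be independent, so the excess over chance is not well measured. All 3 marks were found at 24 of 25 histone deacetylase genes, whose products remove acetyl groups from histones, with HDA9, HDA17 and SRT4 having the longest covered length and HDA4, of 579 bp, unmarked. They were found at 16 of 18 genes of 14-3-3 proteins, which bind phosphorylated partners, and at 53 of 59 genes of the numbered CYP symbol series. The random lists had medians of 13, 8 and 29 genes.

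Genes of leaf function and light response were also marked. All 3 marks were found at 17 of 20 photosynthesis and chlorophyll genes, against a random median of 8. H3K4me3 was at all 20 of them. Among them RCABETA (Rubisco activase) had 92.4% of its length under H3K36me3, and FTRC (ferredoxin-thioredoxin reductase) had 89.7%. The chlorophyll synthesis gene HEMG had 74.6%. Clock and photoreceptor genes had all 3 marks at 34 of 40, against a random median of 19. This group also took in CDF1 and genes of the COL symbol series, so its count is not for clock and photoreceptor genes alone. E2 and GIGANTEA, both of the GIGANTEA family of clock and flowering regulators, had 80.7% and 70.6% of their length under H3K36me3, and the pseudo-response regulator PRR3A had 70.8%. The phytochrome gene PHYE2 was unmarked by these rules, with 157 bp of H3K56ac inside the gene. Among bZIP transcription factors 49 of 77 had all 3 marks, against a random median of 37, with BZIP99 at 93.1% under H3K36me3 and BZIP94 unmarked. This group was inside the limits when random lists were drawn from all protein-coding genes.

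Seed storage, nodulin, nodulation signalling, MADS-box and FT family genes rarely had the full set of marks. Of 29 seed storage, lectin and protease inhibitor genes, none had all 3 marks and none had H3K36me3 (interval up to 11.9%), against a random median of 9 with all 3. H3K4me3 was nevertheless at 17 of the 29, and at 14 of these it was without either other mark. The glycinin gene GY7 carried 2376 bp of H3K4me3, the seed protein gene SBP65 2027 bp and the seed lipoxygenase gene LOX3 1861 bp, all without H3K56ac or H3K36me3. LOX2 was without any peak, and GY3 had 678 bp of H3K4me3 outside the windows counted. Seed maturation proteins had all 3 marks at 3 of 31 genes, PM23, PM37 and LEA-1 (LEA-1 was named after its values were seen). Leghemoglobin and nodulin genes had all 3 marks at 0 of 20, with H3K4me3 at 4 and no mark at 14, N-56 and N-70 among these, while NOD33 carried 1640 bp of H3K4me3 and 1024 bp of H3K56ac. Nodulation signalling genes had all 3 at 0 of 14, with H3K4me3 at 7. The receptor kinase gene SYMRK-ALPHA had 2829 bp of H3K36me3 and neither narrow mark, the single gene of the group with H3K36me3. The transcription factor gene NINA carried H3K4me3 alone, over 2333 bp, and the receptor gene NFR5A was unmarked. Genes of MADS-box transcription factors, several of them with known roles in flowers, had all 3 at 0 of 15. NMHC5 had the longest covered length, with H3K56ac and with H3K36me3 over 39.8% of the gene but no H3K4me3, and was the single gene of the group with H3K36me3. DT2 and SVPL carried H3K4me3 and H3K56ac, and AGL11 was unmarked. In the FT and TFL1 family of flowering regulators 1 of 22 had all 3 marks. That gene, FDL19, has a symbol of another family, and without it the count was 0 of 21.

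Several groups of hormone, transport and defence genes also had few members with all 3 marks. Gibberellin oxidases, which make and inactivate gibberellin, had H3K4me3 at 16 of 21, H3K56ac at 12 and H3K36me3 at 0 (interval up to 16.1%), against random medians of 16, 15 and 8. GA2OX4 carried 2985 bp of H3K4me3 and 4728 bp of H3K56ac, and GA20OX1 and GA20OX2 were unmarked. The auxin carriers PIN and LAX had H3K4me3 at 25 of 28, H3K56ac at 14 and H3K36me3 at 4, which were PIN3A, PIN3B, LAX1 and LAX3 (LAX1 was named after its values were seen). The random medians were 22, 22 and 16, so H3K56ac was also low in this group. All 3 marks were found at 17 of 61 WRKY transcription factor genes, 13 of 66 phenylpropanoid and isoflavonoid genes, 6 of 28 ALMT malate transporter genes and 4 of 43 SWEET sugar transporter genes. They were found at 11 of 85 genes of the CRK symbol series, 3 of 14 PHT1 phosphate transporter genes, 2 of 15 NIP aquaporin genes and 1 of 15 AMT ammonium transporter genes. For 33 LBD transcription factor genes, 21 terpene synthase genes and 19 sieve element occlusion genes the count was 1 each. The PHT1 count of 3 equalled the lower end of the range of random lists, 3 to 10, and PHT1 was counted as below through its percentile of 2.455. PHT1 was inside the limits of random lists without length matching and with windows of 500 bp, and ALMT was inside them when H3K36me3 had to cover at least 50% of the gene. H3K4me3 was present at 50 of the 61 WRKY genes and 12 of the 15 AMT genes, against random medians of 47 and 12. It was below the range of random lists at 58 of the 85 CRK genes (median 69), 16 of the 43 SWEET genes (33) and 4 of the 21 terpene synthase genes (17).

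**Figure D3:**
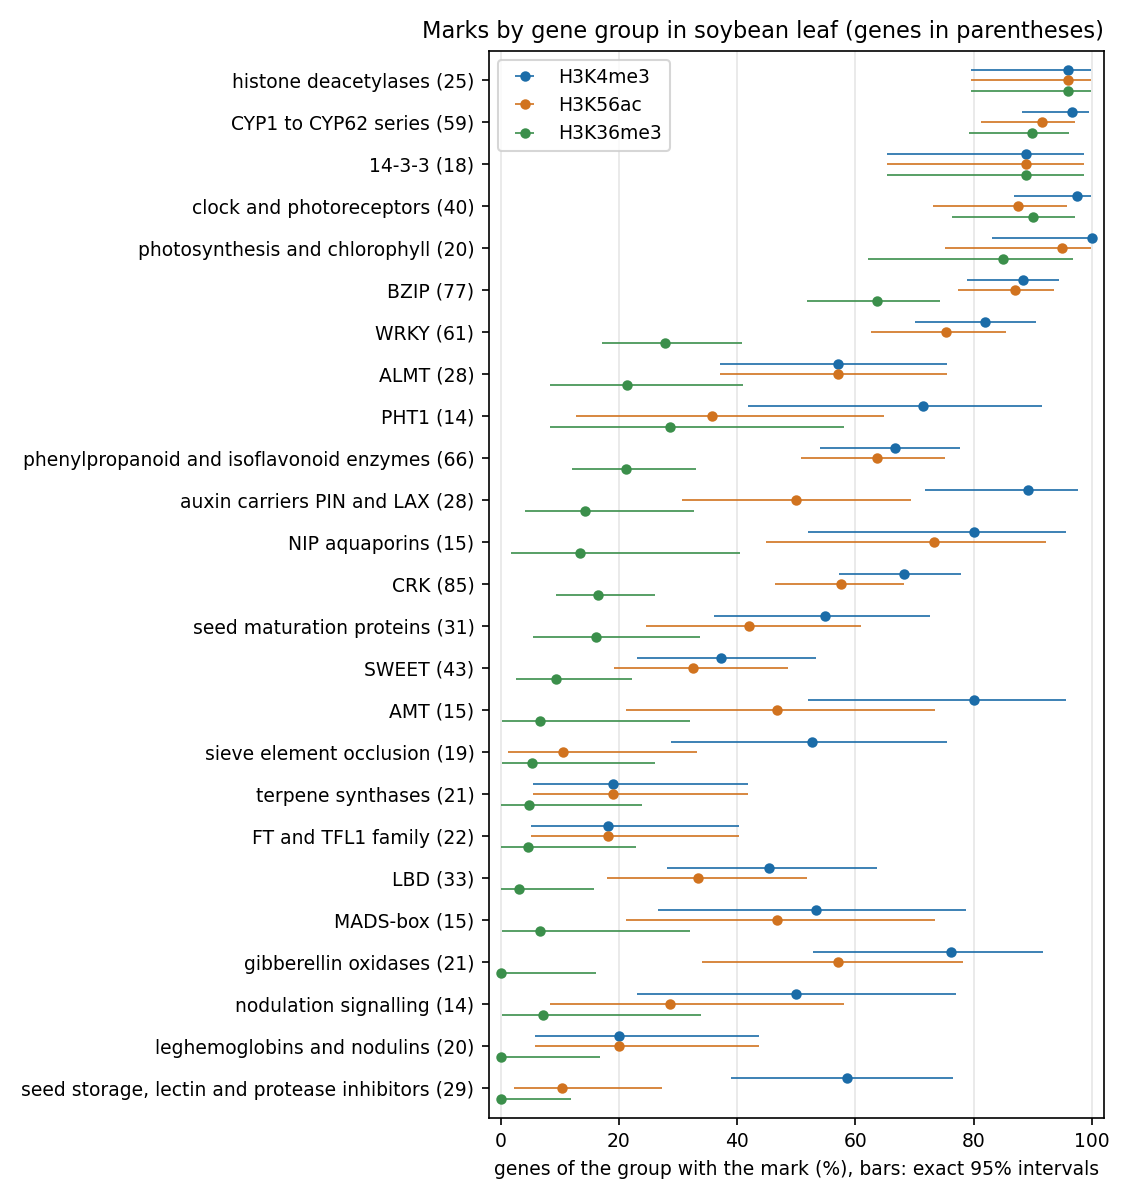
Share of the genes of each group with H3K4me3, H3K56ac or H3K36me3 (horizontal axis, %) for the 25 groups outside the percentile limits of random lists for all 3 marks together (vertical axis). Points are shares and bars exact 95% intervals. Histone deacetylases have each mark at 24 of 25 genes, while seed storage genes have H3K4me3 at 17 of 29 and H3K36me3 at 0.

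The remaining 19 groups lay inside the range of random lists for all 3 marks together. TGA and NF-Y left it in 3 of the 4 alternatives, NAC in 2, and ALDH, IQD, MYB, GASA, PR1 and germin-like in 1 each. All 3 marks were found at 8 of 11 DGK diacylglycerol kinase genes, 8 of 13 WNK kinase genes, 20 of 33 NF-Y genes, 7 of 12 NRAMP metal transporter genes, 37 of 65 IQD genes, 16 of 30 glyoxalase genes and 19 of 37 heat shock factor genes. They were found at 23 of 48 ALDH genes, 15 of 35 genes of the PHR symbol series, 29 of 70 MYB genes, 5 of 15 TGA genes, 12 of 37 GST genes and 4 of 13 expansin genes. The counts were 12 of 43 for NAC factors, 6 of 24 for PIP aquaporins, 2 of 11 for small heat shock proteins, 5 of 33 for GASA peptides, 2 of 18 for germin-like proteins and 0 of 9 for PR1 proteins. For PR1, germin-like and small heat shock proteins the lower limit of the length-matched random lists was 0, so a low count there could not be told from chance. Single marks were low in the first and second of these, with H3K4me3 at 1 of 9 PR1 genes (random median 5) and 4 of 18 germin-like genes (11), and H3K56ac at 0 of 9 PR1 genes (4).

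Of 26 symbols listed for naming before the data were examined, 21 were matched by exact symbol or synonym, to 22 genes. Of these genes, 7 had all 3 marks. These were the light and clock genes E2, E4, PHYA, PHYB, TOC1 and LCL1 (matched through its synonym LHY), and RBCS1, the small subunit of Rubisco (matched through RBCS-1). H3K36me3 covered 87.8% of RBCS1, 68.6% of LCL1, 64.1% of PHYB, 58.7% of TOC1, 50.3% of PHYA and 47.7% of E4. CAB3, a chlorophyll-binding protein gene of 1063 bp, had H3K4me3 and H3K56ac without H3K36me3. The flowering gene FT2A also had these marks alone, with 2208 bp of H3K56ac and 358 bp of H3K4me3. The flowering repressor E1 had a single mark, 158 bp of H3K56ac. H3K4me3 alone was found at the growth habit gene DT1 (266 bp), the nodule number receptor gene NARK (1796 bp), the lipoxygenase gene LOX3, the glycinin genes GY2 (1137 bp), GY4 (746 bp) and GY5 (732 bp), and LOC100787186 (172 bp), which was matched through the synonym SBP. FT5A, LOX2, GY1, SBP2 (through SBP) and the leghemoglobin gene LB1 (through LBC3) had no mark by these rules, although 246 bp of H3K4me3 lay in or near GY1 and 193 bp of H3K56ac in or near SBP2, away from the windows counted.

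The longest H3K36me3 regions each overlapped a single long gene. The longest region, 50000 bp on chromosome 11 from 2861201 to 2911200, overlapped LOC100780088, a gene of 54982 bp, and the next, 49600 bp on chromosome 7 from 2838801 to 2888400, overlapped LOC102669841, of 51152 bp. The others of the 5 longest were 47000 bp in LOC102663906, 45000 bp in LOC100782481 and 41800 bp in LOC100783352. The longest H3K4me3 peak was 5737 bp on chromosome 11 (38379583 to 38385319) in LOC102664765, and 5732 bp of it was also under H3K56ac. The next were 5487 bp in LOC100500448, 5212 bp in LOC100810794, 5068 bp in LOC100806079 and 4998 bp in LOC100793361. The longest H3K56ac peak, 8159 bp on chromosome 3 (35615172 to 35623330), covered a small nuclear RNA gene and a small nucleolar RNA gene, with 1778 bp under H3K4me3 and none under H3K36me3. Another of 7949 bp on chromosome 8 (1378233 to 1386181) covered 3 small nuclear RNA genes and a pseudogene. The others of the 5 longest, of 8033 bp, 7866 bp and 7329 bp, lay over protein-coding genes, namely LOC100782859, LOC100800225 and the pair LOC100805833 and LOC100806357. None of these 5 was under H3K36me3.

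The fourth comparison counted H3K36me3 regions with no annotated gene. There were 549 of 32195 (1.71%, interval 1.57 to 1.85), where random placement gave 60.6%. They were short, with a median of 1200 bp against 2400 bp at genes, and 479 of them (87.2%, interval 84.2 to 89.9) carried both H3K4me3 and H3K56ac, compared with 75.2% of regions at genes (interval 74.7 to 75.6). Among regions of up to 1000 bp the shares were 89.3% without a gene (interval 84.9 to 92.7) and 53.8% at a gene (interval 52.3 to 55.2). Above 4000 bp they were 63.6% of 22 regions and 80.8%, and the intervals overlapped. The longest with both marks was 9000 bp on chromosome 11 (36906001 to 36915000), 10.0 kb from the nearest annotated gene, LOC100780972. The next were 8600 bp on chromosome 8 (16594201 to 16602800), 3.74 kb from LOC100499982, and 6400 bp on the same chromosome (45870401 to 45876800), 0.271 kb from LOC102667868. Then came 5800 bp on chromosome 6 (7264201 to 7270000), 4.14 kb from LOC100813117, and 5600 bp on chromosome 20 (40483601 to 40489200), 8.27 kb from LOC100817532. Against protein-coding genes alone, 6.53% of regions had no gene. In the longer 50% of each list the share without a gene was 0.453%, and 57.1% of those carried both marks. Of the 31646 regions at a gene, 6868 had neither narrow mark, and 92.4% of these (interval 91.8 to 93.1) lay in a gene that held another H3K36me3 region with both.

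The last comparison placed the 4 lists along the chromosomes. Peaks were concentrated toward chromosome ends in both species. The outer 30% of each soybean chromosome, 15% at each end, held 57.5% of H3K4me3 peaks, 56.8% of H3K56ac peaks and 56.1% of H3K36me3 regions, or 1.92, 1.89 and 1.87 times its share of length. Annotated protein-coding genes had 53.4% there. This held on 19 of 20 chromosomes. Chromosome 13 was the exception, with 28.2%, 27.9% and 27.3% for the 3 marks and 27.2% for genes. In maize ear primordia the outer 30% held 44.5% of H3K4me1 regions (interval 43.9 to 45.1), 1.48 times its share of length, and each of the 10 chromosomes lay between 38.0% and 48.9%. The longest maize region was 41600 bp on chromosome 5 (220481001 to 220522600), followed by 41000 bp on chromosome 7 (33468601 to 33509600) and 38600 bp on chromosome 6 (158247001 to 158285600). Those of 34400 bp and 33400 bp were on chromosome 3 (231831801 to 231866200) and chromosome 1 (235073001 to 235106400). Maize coordinates are those of the authors' list, for which the submitters' processing notes name B73 RefGen_v4. The species, tissue and mark all differ between the maize and soybean lists, so what sets them apart could not be separated.

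**Figure D4:**
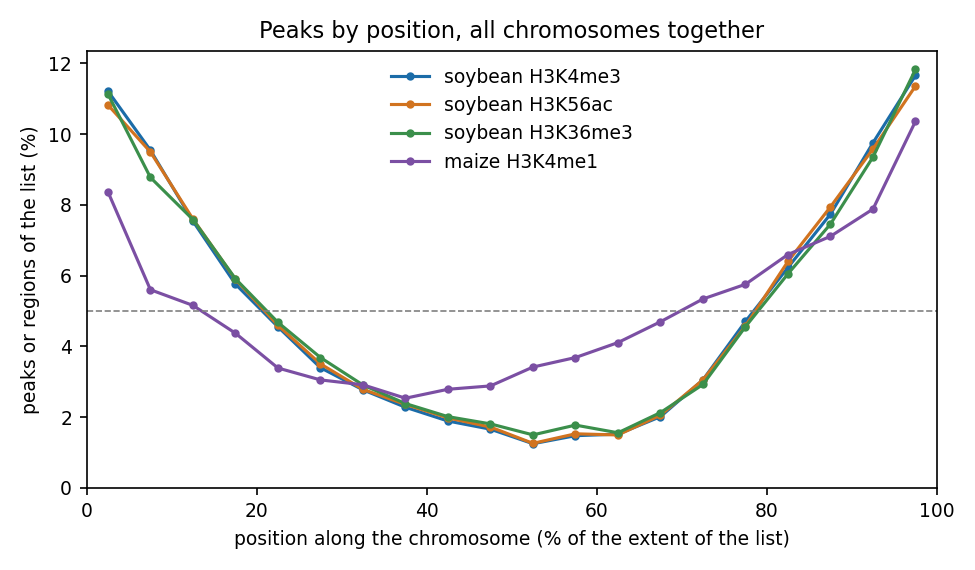
Share of each list (vertical axis, %) in 20 equal bins along the chromosomes (horizontal axis, % of the extent of the list), pooled over all chromosomes. The dashed line at 5% is an even spread. The outer 30% holds 57.5% of soybean H3K4me3 peaks and 44.5% of maize H3K4me1 regions.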

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

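Peaks on scaffolds outside the 20 soybean chromosomes entered no comparison, and their numbers were above the 3 that a count of 0 allows. There were 50 H3K36me3 regions on 18 scaffolds, 91 H3K4me3 peaks on 28 scaffolds and 126 H3K56ac peaks on 32 scaffolds. No test was run on these peaks.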

How the results depend on the processing

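The alternatives were listed before the data were examined, with length already named as the measure for lists without a score. Windows at gene starts became windows at either gene end, and groups became symbol groups, once the gene table was seen. Random lists from all protein-coding genes, H3K36me3 over at least 50% of the gene for gene groups, and the FT family without FDL19 were chosen after seeing the data. No paired analysis was possible because each group holds 1 sample. The planned maize comparisons with genes and gene groups were not run. Of 109 alternatives 11 stayed within the interval of the main value, or within 1.5 times a count, 97 moved outside it and 1 changed direction. Some of the 11 could not move. The shares of genes with H3K4me3 and H3K56ac do not depend on the rule for H3K36me3, nor that with H3K36me3 on the windows at gene ends. Intervals are narrow because the lists are long, and depth, which was unknown, limits what an absent peak shows. The cause of the changes was not tested.

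The change of direction was the ratio of H3K4me3 midpoints near H3K36me3 region ends to random placement, which was 0.698 at 500 bp and 1.15 at 1000 bp. The shares were 11.5% at 250 bp (ratio 0.393), 88.1% at 1000 bp, 35.6% with regions under 1 kb apart joined (0.717) and 14.3% in the longer 50% of each list (0.379).

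For H3K4me3 on H3K56ac, H3K4me3 on H3K36me3, H3K56ac on H3K36me3, and H3K36me3 regions with both, in this order, folds were 11.2, 5.11, 4.34 and 6.14 with an overlap of 50% of the smaller member. They were 10.2, 4.43, 3.89 and 5.05 in the longer 50% of each list, and 4.47, 2.43, 2.15 and 2.89 with placement in the same 1 Mb. Shares with the overlap of 50% were 55.9%, 47.5% and 74.9% for the last 3, and in the longer 50% they were 83.3%, 47.9%, 41.6% and 63.7%.

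At gene ends, H3K4me3 had 73.5% within 500 bp, 91.4% within 2 kb, 76.9% with protein-coding genes alone and 93.0% in the longer 50%. H3K56ac had 64.3%, 85.6%, 68.8% and 85.9%. H3K36me3 at a gene had 93.5% with protein-coding genes alone and 99.5% in the longer 50%. Genes with all 3 marks were 38.3% with H3K36me3 over at least 50% of the gene, 48.2% and 49.9% with windows of 500 bp and 2 kb, and 25.0% in the longer 50%.

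H3K36me3 regions without a gene were 1.24% with no gene within 1 kb, 6.53% against protein-coding genes alone and 0.453% in the longer 50%. Of these 90.7%, 83.3% and 57.1% carried both other marks.

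Peaks near chromosome ends, as times the share of length, were 2.11, 2.06, 2.05 and 1.61 for H3K4me3, H3K56ac, H3K36me3 and maize H3K4me1 in the outer 20%. They were 1.57, 1.57, 1.55 and 1.29 in the outer 50%, and 1.88, 1.86, 1.82 and 1.56 in the longer 50% of each list.

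Gene groups outside the limits numbered 25. The count was 30 without length matching, 26 with windows of 500 bp, 27 with random lists from all protein-coding genes and 27 with H3K36me3 over at least 50% of the gene. In each of these 24 of the 25 were kept, and those lost were PHT1 (the first and second), BZIP and ALMT. Those gained were IQD, NF-Y, GASA, NAC, PR1 and germin-like in the first, NF-Y and TGA in the second, ALDH, NAC and TGA in the third, and MYB, NF-Y and TGA in the fourth, with IQD, NF-Y and MYB above the limits and the others below. Of the other 39 changed values, 22 were folds over random placement, and all 22 stayed above 1.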

Other observations

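Tests on the seed genes and on regions without a gene, and the ratio after random placement of small RNA genes, were chosen after the result was seen; the other 2 small RNA tests were written after the shares by gene type were seen and before their own outcome.

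Aldehyde dehydrogenase genes had H3K56ac more often than H3K4me3 in the windows at gene ends. H3K56ac was at 45 of 48 and H3K4me3 at 34, and 9 genes carried H3K56ac alone by these rules. Random lists of the same size and length deciles had medians of 37 and 38. Of the 9, ALDH18B1, ALDH2B1 and ALDH12A1 had 846, 509 and 164 bp of H3K4me3 inside the gene, away from the windows counted. ALDH3H4 and ALDH2B2, also counted without H3K4me3, had 1295 and 423 bp there. These ALDH genes were named after their values were seen. Sieve element occlusion genes, which encode phloem proteins, had H3K4me3 at 10 of 19 and H3K56ac at 2, against random medians of 16 and 15, with 8 carrying H3K4me3 alone. SEO-F3 carried 2450 bp and SEOF 1336 bp of H3K4me3 alone, and SEOD carried 1292 bp of H3K4me3 and 855 bp of H3K56ac.

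Seed storage genes carried H3K4me3 alone at 14 of 29. Peaks of neighbouring genes reaching into the 1 kb windows are argued against, since H3K4me3 lay inside the gene itself at 14 of 14. Weak calls near the limit of the peak caller stay open. The median H3K4me3 length at these genes was 808 bp, between the median of 610 bp and the upper quartile of 980 bp of the 3165 genes with H3K4me3 alone, and below the 1227 bp of genes with all 3 marks. Reads shared between near-identical seed gene copies were not tested, since the lists hold no reads. With 1 tissue per species no biological explanation was tested.

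H3K36me3 regions without an annotated gene mostly carried both other marks. Spread from a neighbouring annotated gene is argued against as the whole source, because 399 of 549 (72.7%, interval 68.7 to 76.4) had no annotated gene within 1 kb. Background calls scattered over the genome are argued against by the share with both marks, 87.2%, where the same regions placed between genes in the same 1 Mb gave a median of 3.64% and at most 6.01% over 200 placements. The regions were spread over 364 windows of 1 Mb, with at most 6 in one. Transcribed units missing from the gene table are a hypothesis that may account for them; it was not tested, and copied sequences were not tested either, since no genome or RNA data were used.

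Transfer RNA and small nuclear RNA genes with no other gene within 2000 bp had H3K56ac at 49 of 239 and H3K4me3 at 20, a ratio of 2.45 (interval 1.75 to 2.91). Peaks of neighbouring annotated genes stay open as a source of the excess at small RNA genes with neighbours, since places away from every gene already gave a ratio above 1 and the test could not decide. By its limit as written, the test would have argued against this source. It was set aside as unable to decide after its result was seen. H3K56ac peaks lying between genes more often than H3K4me3 peaks is a candidate explanation of the ratio, since the same genes placed at random at least 2000 bp from any gene in the same 1 Mb gave 2.18. The share with H3K56ac itself was 20.5% (interval 15.6 to 26.2), above the median of 10.0% and the maximum of 15.5% over 200 random placements. That background therefore does not account for all of it. H3K4me3, at 8.37% (interval 5.19 to 12.6), was above its random median of 4.60% but below its random maximum of 10.5%. Whether an excess over background was particular to H3K56ac could therefore not be told. The first test written for H3K56ac peaks between genes measured the share with H3K56ac, and the test of the ratio was added once that was seen.

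In the maize list, 1964 of the 2286 regions off the 200 bp grid had a single end off it and 322 had both. The median length was 2610 bp off the grid and 4000 bp on it. An off-grid right end was followed by a region with an off-grid start in 17.4% of cases, where 5.43% of all starts were off the grid.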
